A study of Mus musculus with 18 samples.

How the data were processed

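Gene expression was measured on 18 Affymetrix arrays of 22690 probe sets each, hybridised with biotin-labelled cRNA from mouse dendritic cells grown from bone marrow. Per the labels' protocols, marrow was cultured for a week or more with medium conditioned by B16 melanoma cells that secrete GM-CSF, the growth factor that turns marrow precursors into dendritic cells, and cultures were used once nearly all cells carried the dendritic cell marker CD11c. Cells of 3 conditions (wild type, wild type with the calcium chelator EGTA, and Cd14-deficient) were harvested without LPS or after 2, 4, 6, 12 and 24 h of LPS. Each array was made from 3 µg of RNA, which gave 81 to 150 µg of cRNA. The RNA integrity number (RIN), per the labels, was 8.8 and 8.7 for the EGTA cells at 12 and 24 h and 9.3 to 10 for all other arrays.

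The deposited values are linear intensity values, 1 per probe set and array. Per the submitters' processing notes the authors used MAS5, which summarises the perfect-match and mismatch probes of a probe set on each array by itself. Its version and the scaling target are not given in the sources used here. Trimmed means of the arrays ran from 330.33 (Cd14-deficient, 12 h) to 472.07 (Cd14-deficient, no LPS), so the arrays did not share a scale. A rule fixed in advance called for quantile normalisation in that case, and levels and changes in the report are quantile-normalised log2(value + 16) unless another scale is named, while the quality values of the arrays are deposited intensities. A change on this scale understates the fold change of genes near the added 16.

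Probe sets were named through the annotation table of the array. Of the probe sets, 20393 had 1 gene, 691 had several and 1606 had none, and only those with 1 gene were used for named results. Of these, 20364 had a gene identifier present in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols had to be renamed. That table was used for names and for which genes neighbour each other. No genome build is named with the arrays, so no coordinates are given. A gene was read from its probe set with the highest mean over the 18 arrays, which gave 12394 genes. A gene was tested when it lay above its array's median on at least 2 of the fitted arrays, which left 6929 genes over the 15 LPS arrays and 7056 over all 18.

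Tests were run in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The conditions were compared over the 15 LPS arrays in 1 fit with LPS time as a block, so that the 5 times served as the replicates and the scatter of the condition differences between times as the error (8 residual degrees of freedom). The effect of LPS was fitted over all 18 arrays with the condition as a block, as 1 contrast per time and their mean, so that the 3 conditions served as the replicates (10 residual degrees of freedom). Early (2, 4 and 6 h) against late (12 and 24 h) condition effects and differences in LPS induction between conditions were fitted as interaction terms, with 6 and 8 residual degrees of freedom. In the induction fit the lone unstimulated array of a condition was assumed to vary like the LPS arrays. The unstimulated cells had been plated for 24 h, so only the 24 h contrast of LPS matches them in time since plating. The unstimulated arrays alone were not tested against each other. Errors given as ± are standard errors of the fit, and changes are condition minus wild type or LPS minus no LPS.

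No label says that the arrays of a condition came from separate cultures or animals, and no condition and time was measured again. The p-values therefore measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

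For the gene groups, 28 lists were fixed before the data were examined, among them lists of marker genes of other cell types that a marrow culture can hold. Lists with at least 3 tested members were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of that comparison, and again with a correlation estimated from the arrays. The fry test was run beside them. The comparisons, the lists, the rule for named genes and the alternative settings, other than those given at the end as added, were set before the data were examined. That rule takes Cd14, the 8 largest rises and 8 largest falls of a comparison among genes past the threshold with the same sign at all 5 times (for LPS, in all 3 conditions), and up to 4 genes with the smallest p in each list. It also takes 18 genes chosen from knowledge of the pathway and up to 10 genes each way that changed in both comparisons. For the unstimulated arrays it takes the 5 largest differences each way among genes above the median of both arrays, and a list's median was ranked among 10000 random lists matched on expression. The few genes named outside the rule are said to be so.

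The steps were tested on simulated data with 200 changed genes. For Cd14-deficient against wild type over 6929 genes, 60 of 67 genes changed 1.5-fold, 65 of 67 changed 2-fold and 66 of 66 changed 4-fold were recovered, and 12 of 203 calls were false (5.91%). For EGTA the corresponding numbers were 59 of 67, 65 of 67 and 66 of 66, with 10 false among 200 calls. For the early against late Cd14 effect 27 of 67 genes changed 1.5-fold and 59 of 67 changed 2-fold were recovered, for the EGTA one 30 and 56 of 67. For the difference in LPS induction, over 7056 genes, 13 of 67 genes changed 1.5-fold and 42 of 67 changed 2-fold were recovered for Cd14 deficiency, and 14 and 42 of 67 for EGTA. In the list test, 1 shifted list among 20 was found, with 0 false lists. The noise was drawn for each gene by itself, so the members of a simulated list were not correlated. The list test therefore does not show how often correlated lists are called falsely.

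The alternatives were median centring, other added constants (1 and 64), other filters, all probe sets of a gene, other variance models, and array weights. There were also fits without the time block, with the unstimulated arrays or with only the conditions compared, RIN as a covariate, a fold threshold, and each array and each time left out. Added after the data were seen were the deposited values with no further scaling, leaving out the EGTA arrays of 12 and 24 h, and median centring for the interaction terms and lists. Hybridisation controls and probe sets without a gene entered no named result.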

Results

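The series followed dendritic cells, the antigen-presenting cells that alert T cells, through a day of exposure to lipopolysaccharide (LPS), the bacterial cell wall component sensed by the receptor TLR4 with the help of the surface protein CD14. It compared wild type cells, wild type cells given LPS with 2 mM EGTA, which binds extracellular calcium, and cells without CD14. Its design text describes the pair of inhibited conditions as a way to pick out effects of calcium flux, apart from the lost TRIF signalling of cells without CD14 and from other actions of EGTA. Its title names the calcium-dependent transcription factor NFAT. Each condition was measured on 1 array without LPS and on 1 array after each of 2, 4, 6, 12 and 24 h of LPS, which makes 18 arrays. The labels state 1 µg/ml of LPS for both wild type conditions and no concentration for the cells without CD14. The unstimulated array of the EGTA series names EGTA in its title, while its protocol mentions plating alone. Unstimulated cells were harvested 24 h after plating, and the LPS protocols give no time between plating and LPS, so contrasts with unstimulated cells at 2 to 12 h may also hold effects of time since plating.

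Median intensity ran from 77.9 (wild type, 4 h) to 127 (the unstimulated EGTA array), and the actin 3' to 5' ratio from 1.05 to 1.19. The unstimulated EGTA array stood apart from the other 17 at the dim end, with a 1st percentile of 3.63 against at most 0.939 and 3311 probe sets under an intensity of 16. Its median correlation with the other arrays was 0.927, the lowest of all arrays, where the highest was 0.976. No pair among the 153 pairs of arrays held identical values.

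Cd14 itself followed the labels on every array. In wild type cells it was at a log2 level of 12.65 without LPS and 13.23, 13.06, 13.00, 12.79 and 13.28 after 2 to 24 h, and with EGTA at 12.52, 13.02, 12.78, 12.71, 12.49 and 12.96. In Cd14-deficient cells it was at 5.40 without LPS and 4.35, 4.48, 4.28, 5.83 and 5.38 after LPS. The mean difference under LPS was -8.21 ± 0.24 (adjusted p = 1.8e-10, lower at 5 of 5 times), and without LPS it was -7.25. With EGTA the Cd14 difference was -0.28 ± 0.24, which did not pass the test (adjusted p = 0.488), though Cd14 was lower with EGTA at 5 of 5 times. The error is pooled over the 3 conditions and so holds the scatter of the Cd14-deficient arrays (4.28 to 5.83). A small fall of Cd14 with EGTA therefore cannot be judged by this test.

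**Figure D1:**
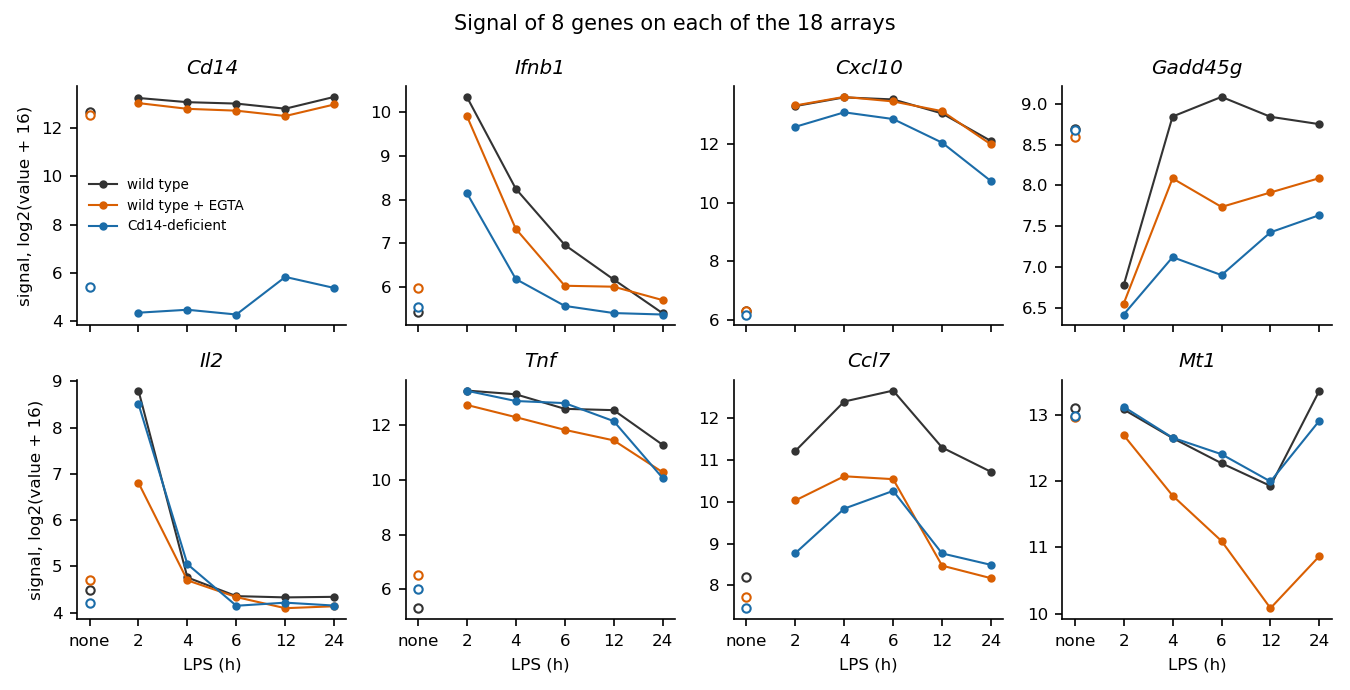
Log2 signal of 8 genes (vertical axes, each with its own range) against hours of LPS (horizontal axis, unstimulated cells at the left as open points) on each of the 18 arrays, in wild type (black), EGTA (orange) and Cd14-deficient cells (blue), 1 array per point. Ifnb1 reached 10.34 at 2 h in wild type cells and 8.15 without CD14, Il2 was at 8.80, 6.81 and 8.51 at 2 h in wild type, EGTA and Cd14-deficient cells, and Mt1 at 24 h was 2.49 lower with EGTA.

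Inflammatory and interferon genes were far higher after LPS than in unstimulated cells in all 3 conditions. Averaged over the 5 times, the interferon-induced gene Ifit1 rose by 7.10 ± 0.27 on the log2 scale (adjusted p = 1.2e-11, 3 conditions, 15 LPS arrays against 3), the T cell chemokine Cxcl10 by 6.55 ± 0.13 (adjusted p = 6.6e-15) and the cytokine Il6 by 6.46 ± 0.12. Rises of similar size were those of U90926 (6.42 ± 0.30), Tnf (6.21 ± 0.26), the cyclooxygenase Ptgs2 (5.97 ± 0.14), Cmpk2 (5.78 ± 0.23) and the neutrophil chemokine Cxcl1 (5.74 ± 0.33). The largest falls were those of the chemokine receptor Ccr2 (-3.95 ± 0.17), the AP-1 subunit Fosb (-3.79 ± 0.24), the transcription factor Klf4 (-3.48 ± 0.23) and the lectin Clec10a (-3.0 ± 0.16). They were followed by Pald1 (-2.88), Rgs2 (-2.86), the adhesion molecule Cdh1 (-2.78) and the arginase Arg1 (-2.71). Among the genes chosen in advance, Cd40 rose by 5.04, Il12b by 4.11, Il10 by 2.68, the prostaglandin synthase Ptges by 2.11, the costimulatory Cd86 by 1.42, the homing receptor Ccr7 by 1.17 and Ddit3 by 0.40, while Nr4a1 (-1.13), Gadd45g (-0.91) and Mt1 (-0.83) fell. These are means over the 3 conditions. Under LPS Gadd45g was lower in both inhibited conditions than in wild type, and Mt1 was lower with EGTA, as given below. In wild type cells Gadd45g was at 6.78 at 2 h and between 8.75 and 9.08 later. The mean falls of Gadd45g and Mt1 therefore need not hold in wild type cells.

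Some changes were larger at 2 h than at 24 h, and the early times also differ from the unstimulated cells in time since plating. Ifnb1, which encodes interferon beta, was 4.90 above its unstimulated level in wild type cells at 2 h, 2.81 at 4 h and -0.03 at 24 h, and its mean rise was 1.20 (adjusted p = 0.00195). Il2, a cytokine that dendritic cells make briefly after LPS, was 4.31 above at 2 h in wild type cells and between -0.17 and 0.26 at all later times. The 2 h rise of Il2 over the 3 conditions passed the test (3.57, adjusted p = 9.84e-06), and its mean over all times did not (0.65, adjusted p = 0.101). Mt2 (-0.44, adjusted p = 0.127) and Tia1 (0.03, adjusted p = 0.707) did not pass either.

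By gene group, all 29 tested members of the type I interferon response list rose (median 3.77, camera adjusted p = 1.05e-20, and adjusted p = 0.0832 with an estimated correlation), among them Ifih1 (3.77). All 27 NF-kB inflammatory genes rose (median 2.75, adjusted p = 3.90e-22), with Il1a at 5.66 and Ccl3 at 3.20, as did all 20 dendritic cell maturation genes (median 1.69, adjusted p = 5.25e-14), with Cd274 at 1.75 and Marcksl1 at 2.27. Of 10 MHC class I genes 9 rose, such as Tap1 (2.04) and Psmb10 (0.99), with a median of 0.73 (adjusted p = 1.77e-05). These last 3 lists kept their call with an estimated correlation (adjusted p = 0.0117 each). Of 27 cell cycle genes 26 fell (median -1.30, adjusted p = 3.32e-09, and 0.0525 with an estimated correlation), among them Birc5 (-2.15), Rrm2 (-1.87), Ube2c (-1.82) and Ccnb2 (-1.81). Of 13 granulocyte markers 11 fell, such as the granule genes Ltf (-1.95) and Ngp (-1.50), while Lcn2, which LPS also induces, rose by 1.01 (adjusted p = 0.0371, and 0.363 with an estimated correlation). Glycolysis and hypoxia genes fell in 14 of 18 cases and rose in 3 (adjusted p = 0.0236, and 0.419 with an estimated correlation), with Vegfa at -1.97 and Tpi1 at -1.22 against Hk2 at 0.85. Immediate early genes fell in 12 of 19 cases and rose in 4 (adjusted p = 0.0480, and 0.419 with an estimated correlation), with Fos at -2.37.

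Among 11 genes of the LPS receptor and TLR4 adaptors, 7 rose, such as Ikbke (2.49), Ly96 (1.09) and Myd88 (0.87), and Tlr4 itself, picked after its values were seen, fell (-0.82). That list's median of 0.24 (adjusted p = 0.0419, and 0.0992 with an estimated correlation) turned to -0.01 without further scaling. The remaining tested lists did not pass. They were NFAT targets (6 rose, 5 fell of 13, adjusted p = 0.215), apoptosis (13 rose, 6 fell of 27, adjusted p = 0.0573), and MHC class II (1 rose, 5 fell of 8, adjusted p = 0.180). The macrophage markers (1 rose, 7 fell of 11, adjusted p = 0.130) did not pass, nor did the dendritic cell markers (2 rose, 5 fell of 9, adjusted p = 0.288), calcium handling (3 rose, 7 fell of 14, adjusted p = 0.629) and cholesterol synthesis (2 rose, 5 fell of 15, adjusted p = 0.478). The last were NRF2 and iron (4 rose, 2 fell of 11, adjusted p = 0.225), ER stress (5 rose, 3 fell of 20, adjusted p = 0.660), actin and adhesion (9 rose, 8 fell of 24, adjusted p = 0.660), mast cell and basophil markers (1 of 4 fell, adjusted p = 0.899), genes named by the study (1 rose, 2 fell of 4, adjusted p = 0.697) and metal-responsive genes (1 of 3 fell, adjusted p = 0.660). Adjusted over the list alone, the falls became 8 for apoptosis, 6 for dendritic cell markers and 1 for NRF2 and iron, and the other counts stayed as they were. Single tested genes of other marker lists were Blnk of B cells (1.46), Bst2 and Tcf4 of plasmacytoid dendritic cells (1.91 and 1.30), Car2 of erythroid cells (1.08) and Xist of the sex-linked list (-0.56). No member of the T and NK cell or B16 melanoma lists passed the filter.

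In counts, which at 2 to 12 h cannot be parted from time since plating, 2917 of 7056 genes differed from unstimulated cells at 2 h, 4290 at 4 h, 4233 at 6 h, 3992 at 12 h and 3684 at 24 h. By the mean of the times 4373 did (1925 higher and 2448 lower, of which 514 and 402 by at least 2-fold). The split between higher and lower calls depended on the scaling. The 2 h contrast gave 1155 higher and 1762 lower as reported, 1863 and 790 with median centring, and 583 and 2779 without further scaling. For the mean of the times median centring gave 2439 and 1514, and no scaling gave 921 and 3707. For the later times the numbers of higher and lower genes with median centring were 2341 and 1588 at 4 h, 2243 and 1588 at 6 h, 2218 and 1380 at 12 h and 1995 and 1287 at 24 h. The reported ones were 1804 and 2486, 1840 and 2393, 1913 and 2079, and 1867 and 1817, and no scaling gave 932 and 3636, 941 and 3411, 1014 and 2419, and 728 and 2792. Median changes of all genes were -0.09 at 2 h as reported, 0.11 with median centring and -0.32 without scaling, and the large changes named above exceed these shifts.

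Under LPS, Cd14-deficient cells held less mRNA of interferon beta and of several chemokine and inflammatory genes than wild type cells. Nos2, the inducible nitric oxide synthase, was 5.77-fold lower over the 5 times (log2 change -2.53 ± 0.35, adjusted p = 2.8e-04, lower at 5 of 5 times), and Ccl7, a monocyte chemokine, was 5.41-fold lower (-2.44 ± 0.20, adjusted p = 3.1e-06, 5 of 5 times). Ifnb1 fell by 1.29 ± 0.26 (adjusted p = 0.00276), with differences of -2.19, -2.06, -1.39, -0.77 and -0.03 from 2 to 24 h, and Cxcl10 by 0.85 ± 0.10 (adjusted p = 7.42e-05). The stress-response gene Gadd45g fell by 1.36 ± 0.19 (adjusted p = 2.38e-04) and the anti-inflammatory cytokine Il10 by 1.05 ± 0.24 (adjusted p = 0.00569). Cd40 (-0.37 ± 0.06, adjusted p = 5.46e-04), Ptgs2 (-0.46 ± 0.15, adjusted p = 0.0319) and Il6 (-0.38 ± 0.13, adjusted p = 0.0414) fell by less. Leaving out 1 array ended the Il6 call for 9 of the 15 arrays (log2 changes of -0.42 to -0.30 wherever 1 array or 1 time left out ended it) and the Ptgs2 call for 4 of 15.

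Many of the largest differences between cells without CD14 and wild type cells were also present without LPS. Of the genes called and at least 2-fold different under LPS, 56 differed by at least 2-fold in the same direction without LPS and 81 did not. Besides Cd14, Nos2 and Ccl7, the largest falls under LPS were those of Rpgrip1 (-4.81 ± 0.12, adjusted p = 9.3e-11), Erdr1 (-3.38 ± 0.25), Rgcc (-2.72 ± 0.17), the neuropeptide gene Cck (-2.56 ± 0.13) and the peptide transporter Slc15a2 (-2.44 ± 0.18). In unstimulated cells these differed by -4.67, -4.17, -1.39, -2.35 and -3.17. The largest rises were those of BC018473 (4.34 ± 0.24, adjusted p = 1.5e-07), BC023105 (2.65 ± 0.16), the carbonic anhydrase Car4 (2.33 ± 0.16) and the anion exchanger Slc26a4 (2.31 ± 0.29), with unstimulated differences of 5.16, 2.70, 2.33 and 1.04. Adi1 (2.12 ± 0.15), S100a4 (1.73 ± 0.30), the scavenger receptor Marco (1.67 ± 0.13) and Rnase2a (1.55 ± 0.09) followed. The other probe sets of Adi1 pointed the opposite way (-1.27 and -0.51). Without LPS Ccl7 differed by -0.75, and Nos2 lay near the floor of the scale in both (4.17 and 4.14).

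In the type I interferon response list 27 of 29 genes fell in Cd14-deficient cells (29 of 29 adjusted over the list alone), with a median of -0.99 (camera adjusted p = 2.49e-18, and adjusted p = 0.201 with an estimated correlation). Its members with the smallest p were Isg20 (-1.67 ± 0.11, adjusted p = 4.9e-07), Cxcl11 (-1.72), Gbp3 (-0.88) and Mx1 (-1.13). The list's median difference was -1.97 at 2 h and between -0.90 and -0.59 from 4 to 24 h, and without LPS it was -0.29. MHC class I genes fell in 7 of 10 cases, among them Tap1 (-0.56), Psmb10 (-0.52), Tapbp (-0.32) and Psme1 (-0.23), and this list alone kept its call with an estimated correlation (adjusted p = 3.38e-05, and 0.0303 with an estimated correlation). Of 20 dendritic cell maturation genes 9 fell and 1 rose (12 and 2 adjusted over the list alone), with Il15 at -1.22, Cd274 at -0.74 and Socs1 at -0.73 (adjusted p = 4.57e-04, and 0.316 with an estimated correlation). The NF-kB list changed less, with 6 falls and 2 rises among 27 genes (median -0.13, adjusted p = 0.0385, and 0.529 with an estimated correlation). Ccl4 (-0.55), Il12a (-0.47) and Il1rn (-0.38) fell and Relb (0.26) rose. Without the 24 h arrays this list's adjusted p was 0.401 and without the 12 h arrays 0.0698. Its median difference was -0.57 at 24 h and between -0.13 and 0.05 before. Tnf (-0.33, adjusted p = 0.123) and Il12b (-0.21, adjusted p = 0.167) did not pass.

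**Figure D2:**
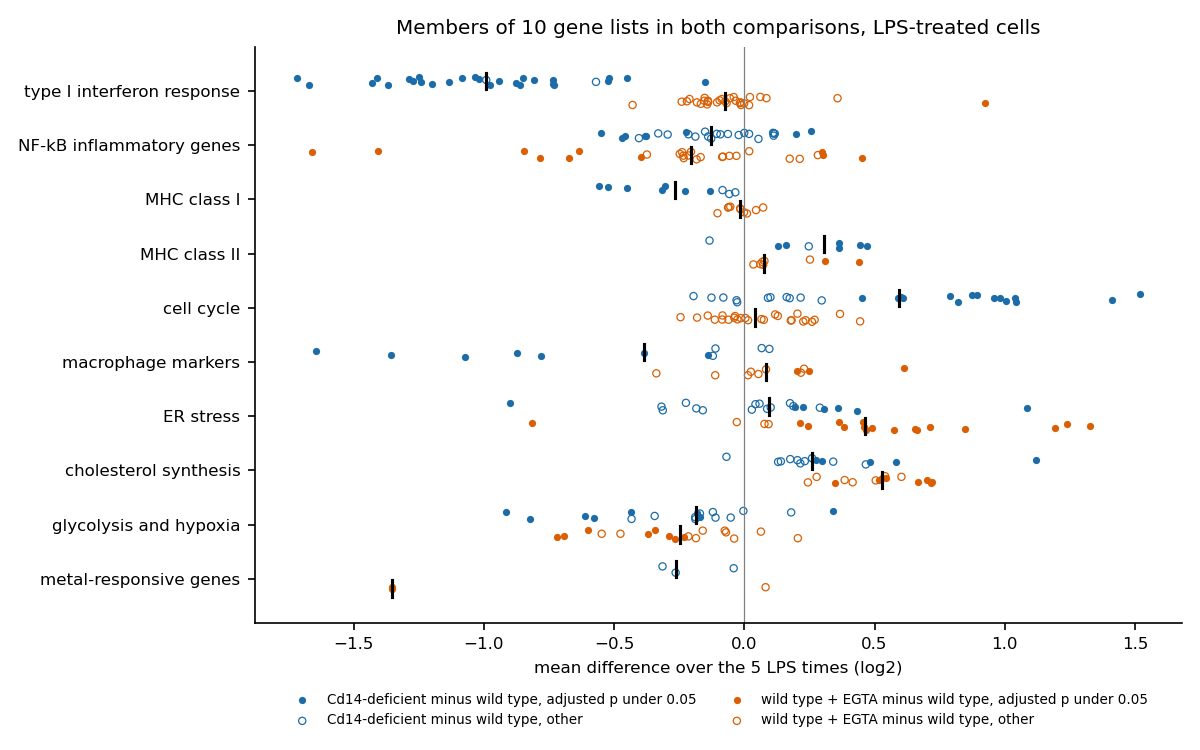
Mean log2 difference over the 5 LPS times (horizontal axis) of each tested member of 10 gene lists (vertical axis) in Cd14-deficient (blue) and EGTA-treated cells (orange) against wild type; filled points passed the test, open points did not, and the black bar is the list's median. Interferon genes had a median of -0.99 without CD14 and -0.07 with EGTA, and ER stress genes of 0.09 and 0.46.

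Genes of antigen presentation by MHC class II and of cell division were higher in Cd14-deficient cells. Of 8 MHC class II genes 6 rose (7 adjusted over the list alone), such as H2-Ab1 (0.47), the class II transactivator Ciita (0.45), H2-Eb1 (0.36) and Cd74 (0.16), with an adjusted p = 0.0109 (0.334 with an estimated correlation). Of 26 cell cycle genes 15 rose and 0 fell, with Ube2c at 1.52 (adjusted p = 2.0e-07), Cdc20 at 1.41, Ccnb2 at 0.98 and Ccna2 at 0.79 and a list median of 0.60 (adjusted p = 1.39e-05, and 0.201 with an estimated correlation). Cholesterol synthesis genes rose in 5 of 15 cases and fell in 0 (adjusted p = 0.0149, and 0.529 with an estimated correlation), with the sterol carrier Stard4 at 1.12 and Sqle at 0.58. Glycolysis and hypoxia genes fell in 7 of 18 cases (8 adjusted over the list alone) and rose in 1 (adjusted p = 0.00164, and 0.334 with an estimated correlation), with P4ha1 at -0.91, Pfkfb3 at -0.61, Hk2 at -0.43 and Aldoa at 0.34. Apoptosis genes fell in 7 of 27 cases (8 adjusted over the list alone) and rose in 1, among them the death ligand Tnfsf10 (-1.57), Gadd45g, Gadd45b (-0.36) and Cycs (-0.30). The list had an adjusted p = 0.0318 (0.201 with an estimated correlation, and 0.0698 without the 12 h arrays). The other probe sets of Gadd45b gave -0.22 and, for a dim one, 0.06.

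Markers of other cells moved with these groups. Of 11 macrophage markers 7 fell in Cd14-deficient cells, with Apoe at -1.65 (adjusted p = 2.5e-09), C1qc at -1.36, C1qa at -1.07 and Fcgr1 at -0.87 (list adjusted p = 6.07e-04, and 0.10 with an estimated correlation). Of 13 granulocyte markers 5 rose and 2 fell (8 and 2 adjusted over the list alone, adjusted p = 0.188), with the granule protein genes Camp (1.53) and Elane (0.74) above and Mmp9 (-0.70) and Mmp8 (-0.56) below wild type. Mast cell and basophil markers fell in 2 of 4 cases (4 adjusted over the list alone), Cpa3 at -0.47 and Kit at -0.36 (adjusted p = 0.0149, and 0.201 with an estimated correlation). Dendritic cell markers rose in 2 of 9 cases (1 adjusted over the list alone), Kmo at 0.55 and Itgax, which encodes CD11c, at 0.29 (list adjusted p = 0.266). The tested plasmacytoid markers Bst2 (-0.56) and Tcf4 (-0.43) fell, while Blnk (-0.26, adjusted p = 0.0657), Car2 (-0.18, adjusted p = 0.448) and Xist (-0.03, adjusted p = 0.810) did not pass.

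The remaining lists did not pass in Cd14-deficient cells. Of 13 NFAT targets 3 fell, namely Il10, Ptgs2 and the calcineurin regulator Rcan1 (-0.39, adjusted p = 0.0205, a call that ended without each of 6 of the 15 arrays), and the list's adjusted p was 0.188. Of 4 genes that the study is known to have named as NFAT-dependent, which is a choice made on such data and no independent evidence, Gadd45g fell. Nr4a1 (0.09, adjusted p = 0.806), Ddit3 (-0.32, adjusted p = 0.104) and Tia1 (0.13, adjusted p = 0.133) did not pass, nor did the list (adjusted p = 0.275). Il2 was 0.29 lower on the log2 scale at 2 h without CD14 (8.51 against 8.80), and its mean change was -0.10 (adjusted p = 0.830). From 4 h on Il2 lay near the floor of the scale in both (4.15 to 5.05), so this mean cannot judge a difference confined to 2 h. ER stress genes rose in 6 of 20 cases (7 adjusted over the list alone) and fell in 1, with Herpud1 at 1.09, Xbp1 at 0.36 and Calr at 0.19 against Atf3 at -0.90 (list adjusted p = 0.266). NRF2 and iron genes rose in 3 of 11 cases, which were Gclm (0.59), Tfrc (0.44) and Txnrd1 (0.35) (adjusted p = 0.188). Calcium handling genes rose in 5 of 14 cases and fell in 1 (adjusted p = 0.251), with S100a4, the endoplasmic reticulum pump Atp2a3 (0.61), S100a6 (0.34) and the channel gene Orai1 (0.28) above wild type. Actin and adhesion genes rose in 6 of 24 cases and fell in 2, with Flna at 0.49 and Actn1 at 0.33 against Thbs1 at -0.68 and the integrin Itgam at -0.57 (adjusted p = 0.935). The TLR4 adaptor list fell in 3 of 11 cases, Cd14 itself, Ikbke (-0.33) and Tbk1 (-0.19), with an adjusted p = 0.0644 that became 0.0311 with median centring and 0.0277 without scaling. This list holds Cd14, the gene missing from these cells, whose fall was set by the design. The list's p-values therefore do not tell whether its other members shifted. Immediate early genes had 1 rise, Btg2 (0.37), and 1 fall, Atf3 (adjusted p = 0.370). Metal-responsive genes had neither (adjusted p = 0.352), with Mt1 at -0.04 (adjusted p = 0.914) and Mt2 at -0.26 (adjusted p = 0.343). Cd86 (-0.17, adjusted p = 0.0924), Ccr7 (0.10, adjusted p = 0.239) and Ptges (-0.11, adjusted p = 0.793) did not pass.

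Across all genes, 2058 of 6929 (29.7%) differed between Cd14-deficient and wild type cells under LPS, 1184 higher and 874 lower, of which 41 and 96 by at least 2-fold. Median centring turned this split to 823 higher and 1070 lower and the unscaled values to 301 and 1058, and without the time block 49 and 57 were left. Without the 4 h, 6 h or 12 h arrays the number of higher genes dropped to 769, 769 and 764. Among the genes named above with calls near the threshold, the number of the 15 arrays whose removal ended the call was 11 for Itgax and Tbk1, 7 for Relb, 4 for Kmo and S100a6, and 1 for Il12a.

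With EGTA several chemokines and cytokines that LPS induces were lower. Ccl7 was 4.27-fold lower (-2.09 ± 0.20, adjusted p = 5.9e-05, lower at 5 of 5 times) and the activin antagonist Fst 4.19-fold lower (-2.07 ± 0.17, adjusted p = 2.0e-05). The granulocyte growth factor Csf3 was 3.16-fold lower (-1.66 ± 0.30, adjusted p = 0.00326) and Cxcl1 2.65-fold lower (-1.41 ± 0.29, adjusted p = 0.00798). Tnf fell by 0.85 ± 0.15 (adjusted p = 0.00367), with differences of -0.52, -0.83, -0.77, -1.10 and -1.0 from 2 to 24 h. The metallothioneins Mt1 and Mt2, which bind zinc and copper, fell by 1.35 ± 0.23 and 1.35 ± 0.20 (adjusted p = 0.00215 and 0.0010), and Mt1 reached a difference of -2.49 at 24 h. The largest rise was that of the eosinophil chemokine Ccl24 (3.05 ± 0.58, adjusted p = 0.0051, higher at 5 of 5 times).

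Other large changes with EGTA were rises of Gpr31b (2.53 ± 0.25), the TGF-beta receptor Tgfbr1 (1.99 ± 0.18), the nuclease Dnase1l3 (1.91 ± 0.29), Cd244a (1.69 ± 0.38), the adaptor Sla (1.58 ± 0.17), Cd93 (1.47 ± 0.32) and Mpzl2 (1.39 ± 0.26). Falls of this rank were those of Nos2 (-1.80 ± 0.35, adjusted p = 0.00584), the calcium-activated potassium channel gene Kcnn4 (-1.68 ± 0.16), the protease inhibitor Timp1 (-1.61 ± 0.12) and U90926 (-1.37 ± 0.14). Of the genes chosen in advance, Ptgs2 (-0.67 ± 0.15, adjusted p = 0.00994), Ptges (-0.90 ± 0.28, adjusted p = 0.0488) and Gadd45g (-0.78 ± 0.19, adjusted p = 0.0158) fell. Ddit3 (0.66 ± 0.14, adjusted p = 0.00892) and Ccr7 (0.28 ± 0.06, adjusted p = 0.0138) rose. Leaving out 1 array ended the Ptges call for 11 of the 15 arrays and the Gadd45g call for 4 of 15, and the calls of Nos2 (-1.31) and Ddit3 (0.63) ended without the EGTA arrays of 12 and 24 h.

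Il2 at 2 h was 2.00 lower on the log2 scale with EGTA (6.81 against 8.80), 1 array each. Its mean change over the 5 times was -0.50 and did not pass (adjusted p = 0.320). From 4 h on Il2 lay near the floor of the scale in both conditions (4.09 to 4.76). This mean therefore cannot judge a difference confined to 2 h. Other genes that did not pass were Ifnb1 (-0.43, adjusted p = 0.310), Cxcl10 (-0.01, adjusted p = 0.946), Il6 (-0.18, adjusted p = 0.388), and Il10 (-0.14, adjusted p = 0.743). Nor did Il12b (-0.25, adjusted p = 0.166), Cd40 (-0.09, adjusted p = 0.354), Cd86 (-0.00, adjusted p = 0.988), Nr4a1 (0.23, adjusted p = 0.577) or Tia1 (0.09, adjusted p = 0.368) pass.

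Of 20 ER stress genes 16 rose with EGTA and 1 fell (median 0.46, camera adjusted p = 1.89e-10, and adjusted p = 0.240 with an estimated correlation). Herpud1 rose by 1.24 (adjusted p = 3.1e-05), the secreted stress factor Manf by 0.71 and the transcription factor Ddit3 by 0.66, while the member that fell was Atf3 (-0.81). Xbp1 rose by 0.47, and its other probe sets gave 0.53, 0.45 and, for a dimmer one, -0.03. The list's median was 0.31 at 2 h and 0.32 at 24 h and lay between 0.47 and 0.63 in between, while the EGTA arrays of 12 and 24 h had the lowest RIN. Cholesterol synthesis genes rose in 8 of 15 cases and fell in 0 (14 and 0 adjusted over the list alone), with Fdft1 and Cyp51 at 0.72, Stard4 at 0.67 and Mvd at 0.53 (median 0.53, adjusted p = 1.61e-07, and 0.361 with an estimated correlation). That list's median difference was 0.18 at 2 h and 1.03 at 24 h.

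Glycolysis and hypoxia genes fell in 8 of 18 cases with EGTA (11 adjusted over the list alone) and rose in 0, among them the glucose transporter Slc2a1 (-0.72), the lactate transporter Slc16a3 (-0.60), Ldha (-0.37) and Pgam1 (-0.23). The list had an adjusted p = 3.62e-05 (0.361 with an estimated correlation). NF-kB inflammatory genes fell in 7 of 27 cases and rose in 3 (9 and 5 adjusted over the list alone), with Csf3, Ccl4 (-0.79) and Ccl3 (-0.63) below and the adhesion molecule Icam1 (0.45) above wild type (adjusted p = 0.00273, and 0.667 with an estimated correlation). NFAT targets fell in 3 of 13 cases, which were Tnf, Ptgs2 and Ptges, and rose in 0 (median -0.18, adjusted p = 0.0305, and 0.339 with an estimated correlation). Tnf and Ptgs2 are also members of the NF-kB list, so the results of these lists are not separate. The Ptges call ended without each of 11 of the 15 arrays. Of 3 metal-responsive genes Mt1 and Mt2 fell and the zinc exporter Slc30a1 was at 0.08 (adjusted p = 0.0311, and 0.361 with an estimated correlation). MHC class II genes rose in 2 of 8 cases, H2-Oa (0.44) and Ciita (0.31), with a list adjusted p = 0.0489 (0.667 with an estimated correlation), which became 0.889 without the EGTA arrays of 12 and 24 h and 0.223 with median centring. It was also lost without the 12 h arrays (0.0658) and without the 24 h arrays (0.498).

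None of the other lists passed with EGTA. Of 29 interferon response genes 1 rose, Cxcl9 (0.93, adjusted p = 0.0019), and 0 fell (list median -0.07, adjusted p = 0.640, and 0.0389 without the 2 h arrays). Of 4 genes named by the study, Gadd45g fell and Ddit3 rose, and the list was no independent evidence here either (adjusted p = 0.640). Dendritic cell maturation had 1 rise (Ccr7) and 2 falls, Tnfsf4 (-0.69) and Tnfsf9 (-0.49), among 20 genes. Immediate early genes had 3 rises and 2 falls among 19, with Dusp2 at 0.80, Egr1 at 0.59 and Klf6 at -0.24. Apoptosis had 4 rises and 2 falls among 27 (9 and 7 adjusted over the list alone), with the pro-apoptotic Bcl2l11 at 0.85, Birc2 at 0.44, Xiap at 0.32 and Cycs at -0.30. Actin and adhesion genes had 1 rise and 5 falls among 24 (3 and 7 adjusted over the list alone), with Itgav at -0.50, Zyx at -0.42, Itga5 at -0.35 and Myh9 at 0.34, and the other probe set of Zyx gave 0.00. The NRF2 and iron list had 1 fall, Hmox1 (-0.68, adjusted p = 0.0393, a call that ended without each of 7 of 15 arrays), and the TLR4 adaptors had 1 rise, Ikbke (0.28). Macrophage markers had 3 rises among 11, Mertk (0.61), Csf1r (0.25) and Apoe (0.20), granulocyte markers 2 among 13, and dendritic cell markers 1 rise and 1 fall among 9. Mast cell and basophil markers had 2 falls among 4, Mcpt8 (-0.68) and Cpa3 (-0.50) (adjusted p = 0.0570), and Blnk of B cells fell by 0.40 (adjusted p = 0.0189). MHC class I, calcium handling, cell cycle, plasmacytoid, erythroid and sex-linked lists had 0 calls with limma.

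In total 943 of 6929 genes (13.6%) differed with EGTA, 512 higher and 431 lower, of which 35 and 29 by at least 2-fold. Unscaled values gave 469 higher and 182 lower, RIN as a covariate 319 and 237, array weights 842 and 671, and a fit without the time block 28 and 23. The counts rested on single arrays, since without the wild type array of 4, 6 or 12 h they were 307, 312 and 302 higher and 266, 267 and 247 lower. Without the EGTA array of 6 or 12 h they were 281 and 285 higher and 241 and 235 lower, and without all arrays of 4, 6 or 12 h 249, 199 and 215 higher and 221, 177 and 170 lower. Without the EGTA arrays of 12 and 24 h, which had the lowest RIN, 268 genes were higher and 188 lower. The number of the 15 arrays whose removal ended a call was 11 for Apoe, 10 for Ikbke, 7 for Csf1r, 6 for Ciita and Slc16a3, 5 for Egr1, Blnk, Tnfsf9 and Zyx, 4 for Myh9, 3 for H2-Oa, and 2 for Klf6 and Itga5.

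The design text sets out to find genes changed in both inhibited conditions, though such a change does not by itself show an effect of calcium flux. Lower in both were 161 genes, led by the opioid precursor Penk (-1.26 ± 0.08 without CD14 and -1.14 ± 0.08 with EGTA), Atf3 (-0.90 and -0.81), Ccl7 (-2.44 and -2.09), the immune cell receptor Slamf7 (-0.84 and -0.56) and the junction protein Pkp4 (-0.66 and -0.67). They were followed by another junction protein, Tjp1 (-0.94 and -0.85), Sdc3 (-0.62 and -0.45), Fgd6 (-0.71 and -0.84), the histone chaperone Asf1a (-0.55 and -0.50) and Rgcc (-2.72 and -1.10), and also held Nos2, Gadd45g, Ptgs2 and Ccl4. Higher in both were 202 genes, led by Herpud1 (1.09 and 1.24), Marco (1.67 and 1.29), Sephs2 (0.60 and 0.50), the amino acid transporter Slc38a2 (0.51 and 0.65), the translocon subunit Sec61b (0.36 and 0.43), F11r (0.88 and 1.10) and Stard4 (1.12 and 0.67). Gpcpd1 (0.45 and 0.43), Frmd4b (0.89 and 0.70) and Sla (1.07 and 1.58) completed this group. LPS raised 96 of the 161 genes that were lower in both and lowered 26, and it raised 37 and lowered 112 of the 202 that were higher in both. Part of the Cd14 difference was present without LPS, on 1 array each. Its median was -0.23 without LPS and -0.46 under LPS for the genes lower in both, and 0.10 and 0.34 for those higher in both. Without LPS Marco differed by 1.90 and Rgcc by -1.39 in Cd14-deficient cells.

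Independent lists of these sizes would share 54.4 lower and 87.5 higher genes, and opposite calls numbered 42 and 39 where 64.6 and 73.6 would be met. Both comparisons use the same wild type arrays, so their errors are shared. Over all 6929 genes the changes correlated with r = 0.240 across genes, which are not independent replicates, and had the same sign in 61.4% of genes. In 100 simulated sets without effects the correlation was 0.501 (0.471 to 0.539), the same-sign share 66.7% and the number of genes called in both at most 1. That last number is low by construction, since without effects each comparison had at most 1 call each way. It therefore cannot serve as a measure for the observed shared counts. The covariance was 0.0224 against 0.00614 (0.00557 to 0.00691) in the simulation, a difference of 0.0162. With the wild type arrays split, so that CD14 was compared at 2, 6 and 24 h and EGTA at 4 and 12 h, 29 genes were lower and 15 higher in both (6.16 and 3.98 for independent lists, r = 0.166, covariance 0.0177, same sign in 57.2%). The reverse split gave 8 and 6 (2.07 and 1.68, r = 0.185, covariance 0.0190, same sign in 58.6%). The split fits used few arrays and left few residual degrees of freedom, and their calls moved widely. With EGTA 237 genes were lower and 242 higher in the first split, and 23 and 19 in the reverse. For CD14 these numbers were 180 and 114, and 625 and 612.

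The shared counts fell to 100 lower and 57 higher without scaling, to 95 and 128 with RIN as a covariate, to 77 and 108 without the EGTA arrays of 12 and 24 h and to 2 and 4 without the time block. Without the wild type array of 4, 6 or 12 h they were 97, 97 and 88 lower and 109, 102 and 101 higher. Without the EGTA array of 6 or 12 h they were 97 and 95 lower and 111 and 116 higher, and without all arrays of 4, 6 or 12 h 76, 66 and 59 lower and 83, 62 and 68 higher.

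**Figure D3:**
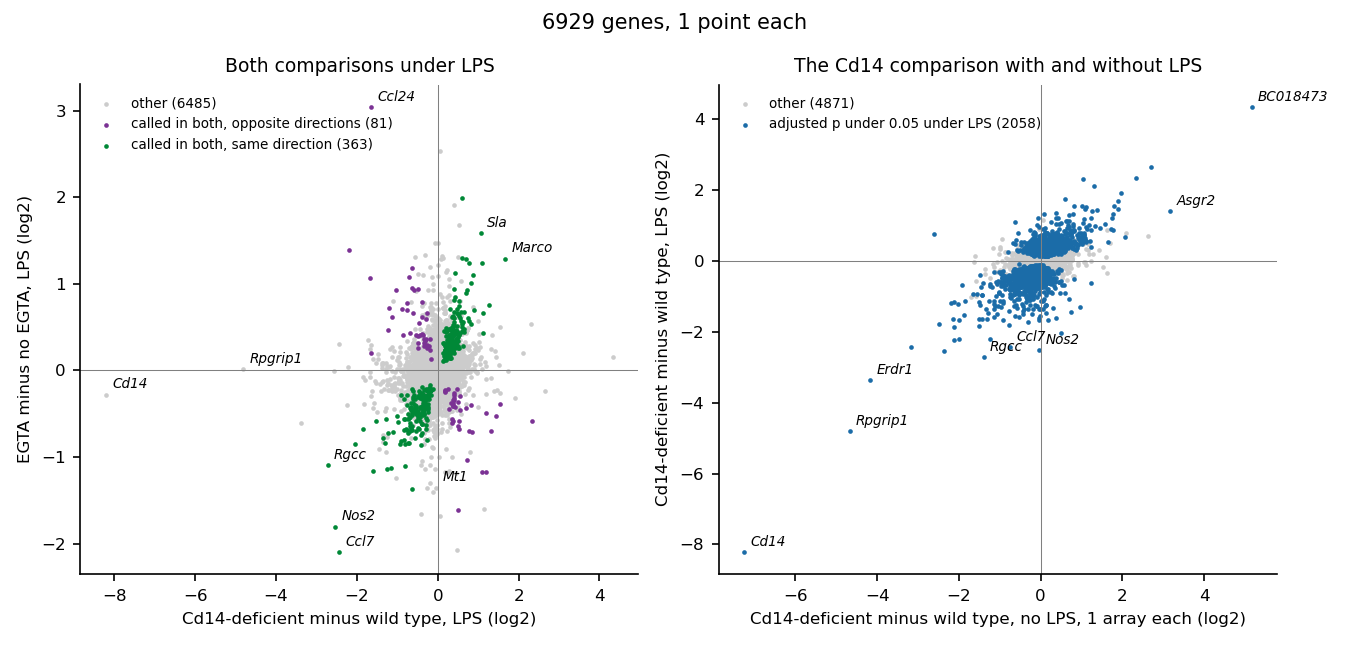
Left, mean log2 difference over the 5 LPS times without CD14 (horizontal axis) and with EGTA (vertical axis), 1 point per gene for 6929 genes, with the 363 genes called in both in the same direction in green and the 81 called in opposite directions in purple. Right, the Cd14 difference without LPS (horizontal axis, 1 array each) against that under LPS (vertical axis), where the 2058 called genes are blue and r across genes was 0.583.

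Set directly against each other, cells without CD14 and EGTA-treated cells differed in 2166 genes under LPS, 1165 higher and 1001 lower in Cd14-deficient cells. Ifnb1 (-0.86, adjusted p = 0.0236), Cxcl10 (-0.84, adjusted p = 6.7e-05), Il10 (-0.91, adjusted p = 0.0124), Ddit3 (-0.98, adjusted p = 2.56e-04) and Gadd45g (-0.57, adjusted p = 0.0328) were lower without CD14 than with EGTA. Mt1 (1.31, adjusted p = 0.0010), Mt2 (1.09, adjusted p = 0.0014), Ptges (0.79, adjusted p = 0.0458) and Tnf (0.51, adjusted p = 0.0228) were higher without CD14 than with EGTA. For Ccl7 (-0.34, adjusted p = 0.216), Nos2 (-0.72, adjusted p = 0.140), Ptgs2 (0.21, adjusted p = 0.293), Herpud1 (-0.15, adjusted p = 0.317), Penk (-0.12, adjusted p = 0.279) and Atf3 (-0.09, adjusted p = 0.360) a difference between the inhibited conditions was not shown. Median centring gave 752 higher and 1269 lower, unscaled values gave 262 and 1912, leaving out the 4 h or 6 h arrays gave 1438 and 1380 genes in all, and a fit without the time block gave 194.

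Without LPS, where 1 array per condition allows no test, the largest differences among genes above the median of both arrays were, for Cd14-deficient cells, the higher levels of the lectin receptors Asgr2 (3.17) and Cd209a (2.62), Car4 (2.33), the caveolin gene Cav1 (2.08) and Mtmr9 (2.08). Furthest below wild type among these genes were the platelet factor Pf4 (-2.02), Epsti1 (-2.0), Mpzl2 (-2.0), the interferon-induced Usp18 (-1.64) and the apolipoprotein Apoc2 (-1.59). The interferon response list had a median of -0.29 in these unstimulated cells, at percentile 0.01 of random lists of matched expression, and dendritic cell maturation of -0.24, at percentile 0. Medians of cell cycle (0.62) and MHC class II (0.30) lay at percentile 100. Random lists hold neither the joint regulation of a list's genes nor the variation between arrays, so these percentiles are not tests. Of the 874 genes lower under LPS in Cd14-deficient cells, 692 (79.2%) were also lower without LPS, and of the 1184 higher genes 879 (74.2%) were also higher. Under the same limit the unstimulated array of the EGTA series differed from wild type most in higher levels of Fbxo36 (2.04), Gpaa1 (1.66), Arid5a (1.48), G6pc3 (1.47) and Commd5 (1.45). Furthest below wild type under it were Rnasek (-1.54), Klk1b27 (-1.34), Rgl2 (-1.24), Clcn5 (-1.24) and H2ac19 (-1.19). Of the 431 genes lower under LPS with EGTA, 305 (70.8%) were also lower on this array, and of the 512 higher genes 313 (61.1%) were also higher. The ER stress median of the array was 0.00, at percentile 56.3, and the correlation across genes between its differences and the EGTA effect under LPS was 0.0790. Small medians on this array also reached outer percentiles, such as interferon response (0.09, percentile 99.27) and immediate early genes (-0.13, percentile 2.96).

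Whether the conditions changed the response to LPS itself was asked with interaction terms. The terms rest on 1 unstimulated array per condition, and 11 of 7056 genes passed for Cd14-deficient against wild type cells, named here after their values were seen. The estimate was lower for the neuropeptide gene Nts (-2.54), Rpl39 (-1.85), Isg20 (-1.84), the pentraxin Ptx3 (-1.72), Atf3 (-1.38), Penk (-1.38), Fpr2 (-1.12) and Tiparp (-0.82) and higher for Klk1b21 (3.36), the itaconate enzyme Acod1 (1.59) and Alas1 (0.70). Without the wild type array of 12 h 3 genes passed, and without the Cd14-deficient array of 2 h 39. For 6 of the 11 the difference without LPS was larger than that under LPS, as for Acod1, which was -1.63 without LPS and -0.04 under LPS. For EGTA 117 genes passed, 62 higher and 55 lower, and for 90 of these the unstimulated difference was the larger. They rest on the lone unstimulated EGTA array, which stood apart at the dim end, and numbered 760 with median centring, 29 without scaling, 74 with 64 added, and 53 to 65 without the wild type or EGTA array of 4, 6 or 12 h. The early and late condition effects differed for 3 genes in Cd14-deficient cells, also named after their values were seen. Gypc (1.00 ± 0.13, adjusted p = 0.0384) and Nrep (1.68 ± 0.22, adjusted p = 0.0384) were below wild type early and above it late, and the haem oxygenase Hmox1 (-1.27 ± 0.18, adjusted p = 0.0484) was above it early and below it late. With limma 0 genes passed without the wild type array of 2, 4, 6 or 24 h, the EGTA array of 2, 4 or 6 h or the Cd14-deficient array of 4 or 6 h, or with no filter, and 39 and 59 passed without the wild type and Cd14-deficient arrays of 12 h. For EGTA 0 genes passed with limma, and 819 had an unadjusted p under 0.05. Without the wild type array of 12 h 76 passed, and without the EGTA array of 12 h 34.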

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

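The splits within times and the tests of DNA from another strain, including the genes around Cd14, of fewer dendritic cells, of a signal shared with CD14 deficiency and of RNA quality for the metallothioneins were chosen after the result was seen. The tests of probe sets, of RNA quality for the ER stress genes, of zinc and of other splits over all arrays were set before their results were seen.

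The 5 LPS times of each condition were checked for a value far from the other 4, over 93 tests, of which 15 were past the limit. Chance passes it in about 5% of groups of like values, but these are different times, so a time course passes it by itself and no number by chance is given. At 2 h Il2 lay far above its later levels on the log2 scale, at 8.80 in wild type (4.33 to 4.76 later), 6.81 with EGTA (4.09 to 4.70) and 8.51 in Cd14-deficient cells (4.15 to 5.05). Gadd45g at 2 h was far below its later levels, at 6.78 in wild type (8.75 to 9.08) and 6.55 with EGTA (7.74 to 8.09), and Tia1 in wild type cells was at 8.02 (8.51 to 8.70). Cd86 at 2 h was at 11.425 in wild type (12.22 to 12.47), 11.695 with EGTA (12.19 to 12.31) and 11.21 in Cd14-deficient cells (12.02 to 12.35). Ccr7 at 2 h was at 11.27 in wild type (12.34 to 12.64) and 11.62 with EGTA (12.59 to 12.94). Il12b at 24 h was far below its other levels, at 11.88 with EGTA (13.03 to 13.44) and 12.135 in Cd14-deficient cells (13.10 to 13.44). The Gapdh 3' to 5' ratio of the EGTA array of 24 h was 0.734 (0.766 to 0.770 on the others). The 1st percentile of intensity on the Cd14-deficient array of 12 h was 0.681 (0.739 to 0.754).

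Interaction terms passed for 3 genes between the early and late effect of Cd14 deficiency, 11 genes between LPS induction without CD14 and in wild type cells, and 117 genes between LPS induction with and without EGTA. The induction terms rest on 1 unstimulated array per condition, on which 6 of the 11 and 90 of the 117 genes differed more than under LPS. For those genes the terms do not show a changed response. Some other genes differed chiefly under LPS, such as Penk without CD14 (0.12 without LPS and -1.26 under LPS) and Fst with EGTA (-0.02 and -2.07). Their unstimulated differences have no replicate either. A signal was also present in probe sets that the report does not use. Of 457 tested probe sets with several genes, 208 differed between Cd14-deficient and wild type cells and 75 with EGTA, and of 564 with no gene, 163 and 79 did.

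Other splits of the 10 arrays of the conditions compared were fitted with the same time block. Among 100 drawn of 126 splits, 1, the real one, had as many calls for Cd14-deficient against wild type (2058, next 161), and likewise 1 for EGTA (943, next 90) and 1 for Cd14-deficient against EGTA (2166, next 291). Of the 100 splits, 88 put both arrays of at least 1 time on the same side, which the real one does not. Swaps within times, added after the result was seen, make 16 splits, too few for a share under 0.05, and the highest counts among the others were 5, 1 and 11. For LPS as 1 term, 1 of 100 drawn of 816 choices of 3 arrays had as many (2920, next 1662), and 1 of 100 drawn of 216 with 1 array of each condition (next 512). The arrays form a time course, so the choices are not alike, and the fit with 1 term is not the reported contrast. These draws therefore do not exclude chance. At each time 1 of 10 splits, the real one, had as many calls, with at most 1 call in any other, and 10 splits are too few for a share under 0.05.

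The pattern of 56 genes that differed at least 2-fold between Cd14-deficient and wild type cells both with and without LPS could come from DNA of another mouse strain, as such mutants can carry, chiefly around the altered gene, but of the 40 tested genes next to Cd14 11 were called (27.5% against 29.7% of all genes) and 0 differed 2-fold. One count of genes with another member within 5 tested genes gave 10 (random sets 0 to 10 in 95% of draws), and another of the most genes on 1 chromosome gave 10 (random sets up to 15, median 7). The last, of the excess over the number expected there, gave 8.16, which 15 of 10000 random sets reached, on the chromosome holding Rpgrip1, Rgcc and Rnase2a, not the one holding Cd14. With 3 tests tried in turn on data already seen, such DNA elsewhere stays open. Nothing points to it among the 20 tested genes on each side of Cd14, but a longer stretch around Cd14 was not tested. The reading of strain variants by probe sets stays open too. Only 17 of these genes had other tested probe sets, of which 18 of 24 (75%) were called in the same direction and 2 in the opposite one. The bar set in advance against this reading was over 75%. If fewer dendritic cells in the Cd14-deficient cultures left more of all other cells alike, the markers of those cells would all rise. But macrophage markers had a median of -0.38 (7 of 11 called lower, adjusted p = 0.10 with an estimated correlation) and granulocyte markers of 0.43 (5 of 13 called higher, 2 lower). These values argue only against an equal rise, and another change in the mix of cells between cultures was not tested and stays open. Cd14 deficiency itself, the biological explanation, was also left open.

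The pattern of ER stress genes raised by EGTA could come from the lower RIN of the EGTA arrays of 12 and 24 h, but without these arrays the list's median was 0.49 against 0.46 with them. A calcium signal that CD14 deficiency also removes stays open: 11 of the 16 genes raised with EGTA were lower in Cd14-deficient than in EGTA-treated cells, but they were picked as high on the same EGTA arrays, and 6 of them were also called higher without CD14. Loss of extracellular calcium by another path, a biological explanation, was not tested.

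The pattern of lower metallothioneins with EGTA was present before the arrays of lower RIN, with a mean difference of Mt1 and Mt2 of -0.91 at 2 to 6 h (-2.02 at 12 and 24 h), which argues against RNA quality. Mt1 was 1.31 higher without CD14 than with EGTA and at -0.04 ± 0.23 against wild type without CD14, which argues against a calcium signal shared with CD14. EGTA also binds zinc, which induces these genes, and less free zinc in the medium could account for the fall, but Slc30a1, also induced by zinc, was at 0.081, and the test cannot tell.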

How the results depend on the processing

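Unscaled values, leaving out the EGTA arrays of 12 and 24 h, and median centring of interaction terms and lists were chosen after the result was seen, and the other alternatives before. The planned quantile alternative is the reported setting. The design names no pairs or cultures, so no paired analysis was possible because the arrays of a condition share only their times, which form the block. Induction differences without the lone unstimulated array of a condition could not be estimated. The number of arrays and dim signals limit what can be seen: 3311 to 5570 probe sets per array had an intensity under 16. The cause was not tested for any change given here, except where fewer arrays, more probe sets or a higher bar are the change itself.

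Each array or time left out gave 764 to 1243 higher and 611 to 902 lower genes without CD14, 199 to 585 higher and 170 to 491 lower with EGTA, 1380 to 2250 between the inhibited conditions, and 59 to 192 lower and 62 to 216 higher in both. It gave 0 to 59 (CD14) and 0 to 76 (EGTA) genes for early against late effects, and 3 to 39 and 53 to 153 for induction. LPS at 2 h without wild type arrays gave 1665.

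Without scaling there were 301 higher genes without CD14, 182 lower with EGTA, 100 lower and 57 higher in both, 921 higher and 3707 lower with LPS (mean), 10 and 14 (early against late), and 20 and 29 (induction). Median centring gave 1514 lower with LPS, 2 for early against late EGTA effects and 760 for EGTA induction. Adding 64 gave 14, 2 and, for EGTA induction, 74, and no filter gave 0 (early against late, CD14) and 5 (CD14 induction). Without the time block there were 49 higher and 57 lower without CD14, 28 and 23 with EGTA, 194 between the inhibited conditions, and 2 lower and 4 higher in both. RIN as a covariate gave 319 higher and 237 lower with EGTA, and 95 lower and 128 higher in both, and leaving out the EGTA arrays of 12 and 24 h gave 268, 188, 77 and 108. Array weights gave 842 higher and 671 lower with EGTA and 332 higher in both, and all 18 arrays 133 higher in both. All probe sets gave 1381 lower without CD14, 701 lower with EGTA, 267 lower in both, 4379, 6782, 6738, 6220 and 5805 with LPS by time, and 3124 higher and 3856 lower with LPS. A 2-fold bar left 41 and 96 without CD14, 35 and 29 with EGTA, 170, 6 lower and 3 higher in both, 561, 1250, 1258, 1100 and 959 with LPS by time, and 514 and 402.

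Unscaled values turned the LPS changes of Tia1 (-0.28) and Cpa3 (-0.35). Another probe set turned Gadd45b (0.058, against -0.22 for a brighter one) and Txnrd1 (-0.0048, against 0.087) without CD14, Xbp1 with EGTA (-0.033, against 0.45 and 0.53) and with LPS (0.14, against -0.65 and -0.61), and Zyx (0.0016) with EGTA. Both other probe sets of Adi1 turned it without CD14 (-1.27, -0.51). Of 5247 named-gene results, past the threshold or not, 5028 kept their sign and side of it with an array left out (190 lost a call and 29 gained one), of 1124 with a time left out 985 (124 lost), of 330 with median centring 306, without scaling 295, without filter 317, with an added 1 or 64 329, without trend 319, with robust variances 327, with array weights 318 and without the EGTA arrays of 12 and 24 h 297, of 227 with RIN 197, with all 18 arrays 208 and without the time block 98 (129 lost), and of 199 on other probe sets 157. Of 88 list results 35 passed, and 5 of these kept their call with an estimated correlation, which lost 30. The fry test lost 4 calls and gained 16, median centring lost 3 and gained 2, and no scaling lost 4 and gained 7. Of 2058 CD14 calls 1683 were shared with median centring, 1140 without scaling and 106 without the time block, 0 of them opposite.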

Other observations

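The genes named here were picked after the result was seen, the values are not explained, and no hypothesis was tested.

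The granulocyte markers had a median change of -0.08 at 2 h and -2.04 at 24 h over the 3 conditions. The cell cycle list was at -0.78 at 2 h and -1.94 at 24 h, and its Cd14 difference was 0.79 at 2 h, 0.12 at 12 h and 0.56 at 24 h. Cholesterol synthesis was at 0.21 at 4 h and -0.93 at 24 h with LPS, while the EGTA difference of this list was 0.18 at 2 h and 1.03 at 24 h. Gypc, which encodes a red cell membrane glycoprotein, differed by -0.69, -0.58, -0.69, 0.43 and 0.26 between Cd14-deficient and wild type cells from 2 to 24 h. Nrep differed by -0.94, -1.14, -0.89, 0.61 and 0.77, and Hmox1 by 0.31, 0.56, 0.57, -0.43 and -1.14.

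Among genes past the test of LPS induction with EGTA, which rests on 1 unstimulated array, Il1b, which encodes interleukin 1 beta, was 0.65 higher without LPS and -0.06 under LPS (induction difference -0.71 ± 0.08, adjusted p = 0.00362). Ggct, an enzyme of glutathione breakdown, was at -0.57 without LPS and 0.94 under LPS, and Crtc2, a coactivator of CREB, at -1.67 and 0.15. The median level of these 117 genes was 7.79 against 8.64 for all tested genes. Unstimulated differences over 2-fold numbered 71 higher and 107 lower in the EGTA series and 72 and 71 in Cd14-deficient cells.

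In unstimulated Cd14-deficient cells the mast cell and basophil markers had a median of -0.51 (percentile 0.32 of random lists), the immediate early genes of 0.16 (99.7) and the dendritic cell markers of 0.27 (99.83). These percentiles rest on 1 array per condition and are not tests.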
